A study of Homo sapiens with 12 samples.

How the data were processed

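The series measured total RNA of OUMS-36T-3F, an established line of human fibroblasts, on 12 whole-transcript arrays in 4 groups of 3. The groups were wild type (WT), HSF1 knockout (KO), HSF1 knockout with chicken HSF1 overexpressed (cHSF1) and HSF1 knockout with chicken HSF3 overexpressed (cHSF3). Per the labels' protocols, cells were grown in DMEM with fetal bovine serum and received no treatment, RNA was isolated with the RNeasy Mini Kit, and biotinylated cDNA was made with the WT PLUS Reagent Kit. Per the submitters' processing notes, the software was Partek 6.6. How the arrays were background-corrected, normalized and summarized is not given in the sources used here, and no scanner files were used.

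The deposited values are 1 signal per probe set and array and were taken as log2, a unit inferred from the values, which lie between 1.77 and 17.6. They were used as deposited, with no further normalization. The table holds 24351 probe sets. Of these, 2903 controls were left out of the tests, namely 612 negative, 2197 positive, 63 ERCC and 31 AFFX control probe sets. The remaining 21448 probe sets were tested. Gene symbols came from the platform annotation supplied with the series, which gives 1 symbol to 17709 of the tested probe sets, several symbols to 0 and none to 3739. The 3739 are unnamed here, not known to lack a gene. The symbols name 17687 genes, of which 20 have more than 1 probe set. For these the probe set with the highest mean over the 12 arrays stands for the gene. Probe sets of the same gene differed in call for 1 gene in each of KO versus WT, cHSF1 versus KO, cHSF3 versus KO and cHSF3 versus cHSF1, and for 4 genes in each comparison of a factor group with WT. HSF2, HSF4, HSPA1B and HSPA8 have no named probe set in the table and were not analysed here.

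Differences between groups were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 12 arrays, so that the 4 groups share 1 estimate of each probe set's spread with 8 residual degrees of freedom. Moderated statistics came from eBayes, whose prior had 3.70 degrees of freedom. Tests were two-sided, and a probe set was called when its Benjamini-Hochberg adjusted p over the 21448 probe sets was under 0.05. The 6 pairs of groups were compared, and a moderated F test asked for any difference among the 4 groups. The median residual SD of a probe set was 0.20 on the log2 scale. The number of arrays limits the precision of every value.

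As the background level of an array, the 95th percentile of its 612 negative control probe sets was used. A gene at or under that level on every array of both groups is given as levels without a fold. Where only the dimmer group lies under it on every array, the fold is given as "at least": the brighter group's mean is set against the mean, over the dimmer group's arrays, of the higher of that level and the gene's own signal.

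Before the data were examined, 25 gene lists were fixed: cytosolic heat shock proteins and cochaperones, TRiC chaperonin and prefoldin subunits, mitochondrial chaperones and proteases, endoplasmic reticulum chaperones and unfolded protein response genes, integrated stress response and ATF4 target genes, proteasome subunits, ubiquitin and autophagy genes, cytosolic ribosomal proteins, respiratory chain and ATP synthase subunits, cell cycle genes, p53 targets, inflammatory and NF-kB target genes, interferon-stimulated genes, extracellular matrix genes, contractile and TGF-beta or YAP target genes, cholesterol synthesis and SREBP target genes, hypoxia and glycolysis genes, oxidative stress and metallothionein genes, immediate early genes, HOX genes, heat shock factor genes, and markers of epithelial, endothelial, leukocyte, and neural, muscle or fat cells. Lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists that qualified, with a correlation estimated from the data as an alternative. The heat shock factor list had 2 measured members and is described without a test.

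The rule for named genes was also fixed before the data were examined. It takes the 10 higher and 10 lower genes with the largest change among called genes whose arrays do not overlap (5 and 5 for the comparisons of factor groups with WT). It adds 13 heat shock genes whatever their values, up to 4 called members with the smallest adjusted p from each list that was called or had at least 3 called members, and the 5 genes with the largest change in both comparisons of each overlap. Not every gene the rule takes is printed. Overlaps between comparisons that share the KO arrays were set beside the overlap of independent lists and beside 20 simulations of unchanged groups that share those arrays. For the calls in KO versus WT that were also called in a factor group versus WT, 20 further simulations, added after seeing the data, shared the WT arrays and set the factor groups at the level of WT.

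The alternatives planned before the data were examined were quantile normalization between arrays, centring each array on its median, leaving out the dimmest 30% of probe sets, fitting the arrays of the compared groups alone, a variance trend with a robust prior, array weights, the replicate number as a block, 1 probe set per gene, a minimum change of 1.5-fold, the estimated correlation, and leaving out each array in turn. A scaling that equalizes the positive control probe sets and a filter on the negative controls were chosen after seeing the data. Other splits of the arrays, shuffles of the calls over neighbouring genes, and a comparison of chaperone genes with other genes are given after the results. The order of genes along chromosomes was taken from the RefSeq annotation of assembly GRCh38.p14, used for neighbours alone. Plots were drawn with Python 3.11.15.

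The scripts were tested on simulated data. In a simulated KO versus WT comparison over 21448 probe sets, 33 of 100 probe sets changed by 1.5-fold and 78 of 100 changed by 2-fold were called, 0 of them in the wrong direction, with 4 false calls (3.48% of the calls). For a simulated shift of 0.3 in the proteasome list, camera called that list and 0 of the others.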

Results

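Heat shock factors are transcription factors that bind heat shock elements, and HSF1 is the main activator of heat shock protein genes in human cells. The series asks which genes depend on human HSF1 and which respond to chicken HSF1 or chicken HSF3 in cells that lack human HSF1. Transcript levels were measured in unstressed OUMS-36T-3F fibroblasts on 12 arrays, 3 for each of 4 groups: wild type (WT), HSF1 knockout (KO), and knockout cells with overexpressed chicken HSF1 (cHSF1) or chicken HSF3 (cHSF3). The labels do not say whether the arrays of a group come from separate cultures, so the p-values measure the spread between these arrays alone, and 3 arrays per group limit the precision. Nor do they say whether the knockout cells or the cells with a factor come from single clones, so a difference between groups is not by itself shown to be an effect of HSF1 or of a chicken factor. No group holds knockout cells handled like the factor groups but without a chicken factor. Effects of introducing a gene therefore cannot be told apart from effects of the factors. Differences are given on the log2 scale with the standard error of the fit, group levels as mean ± SD of 3 arrays, and "rose", "fell", "higher" and "lower" as test results mean a limma adjusted p (Benjamini-Hochberg) under 0.05.

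The arrays were alike in overall signal. The median of the tested probe sets lay between 7.37 and 7.45, the negative control median between 4.46 and 4.63, and between 41.0% and 45.9% of the tested probe sets lay above the 95th percentile of the negative controls. That percentile lay between 8.08 and 8.78. Correlation between arrays of the same group was at least 0.994 across genes, and the highest correlation of any array with an array of another group was 0.995. Of the 21448 probe sets, 6189 (28.9%) differed among the 4 groups. The positive control probe sets did not have the same level in every group: their median was 13.69 ± 0.02 in WT, 13.57 ± 0.02 in KO, 13.49 ± 0.02 in cHSF1 and 13.50 ± 0.04 in cHSF3. Setting these medians equal, a scaling chosen after seeing the data, moves the median of all probe sets by 0.12 in KO versus WT and by 0.20 in both comparisons of a factor group with WT. Changes below are relative to the signal as deposited, and the calls of lists and heat shock genes that this scaling ends, and the called lists whose median it turns, are named. Medians of lists that were not called turn in several cases.

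HSF1 itself was 11.96 ± 0.07 in WT, 9.99 ± 0.015 in KO, 9.95 ± 0.22 in cHSF1 and 9.78 ± 0.12 in cHSF3. It was 3.92-fold lower in KO than in WT (log2 difference -1.97 ± 0.12, adjusted p = 3.58e-07), 4.02-fold lower in cHSF1 (adjusted p = 2.04e-07) and 4.54-fold lower in cHSF3 (adjusted p = 9.40e-08). It did not differ between KO and cHSF1 (adjusted p = 0.915) or between KO and cHSF3 (adjusted p = 0.269). The level stayed above the negative controls on every array. Where the probes lie relative to the edited part of the gene is not stated, so the remaining signal does not show how much intact transcript is left. No probe set is named for a chicken gene, so the amount of the introduced factors is unknown. Of the heat shock factor list, 2 genes were measured, and HSF1 was the called member in KO versus WT.

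A set of chaperone genes was lower in KO than in WT. HSPH1, an HSP110 nucleotide exchange factor, was 2.30-fold lower in KO than in WT (-1.20 ± 0.10, adjusted p = 5.29e-06). HSPE1 and HSPD1, the mitochondrial chaperonin pair, fell by 0.65 ± 0.14 and 0.58 ± 0.08, the small heat shock protein HSPB1 fell by 0.53 ± 0.09, and HSP90AA1, the inducible cytosolic HSP90, fell by 0.50 ± 0.10. DNAJB1, an HSP70 cochaperone, fell by 0.36 ± 0.11 (adjusted p = 0.0411), a call that ends when the positive controls are set equal (adjusted p = 0.135). HSPA1A, the inducible HSP70, had a difference of 0.31 ± 0.12 (adjusted p = 0.121), which passes under that same scaling (adjusted p = 0.0299), and BAG3 one of -0.01 ± 0.09 (adjusted p = 0.948). Of the 33 measured cytosolic heat shock proteins and cochaperones, 15 fell, 2 rose and 16 did not pass, and 17 fell and 4 rose adjusted over the list alone. HSPA4L fell by 1.16 ± 0.12, whereas the small heat shock proteins HSPB8 (1.43 ± 0.09) and HSPB6 (4.61 ± 0.21, with WT above the negative controls on 2 of 3 arrays) rose. The list was lower as a whole (median -0.27, camera adjusted p = 0.00134), with adjusted p = 0.0645 with an estimated correlation. With the positive controls set equal, 10 members fell and 4 rose, with a median of -0.14.

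**Figure D1:**
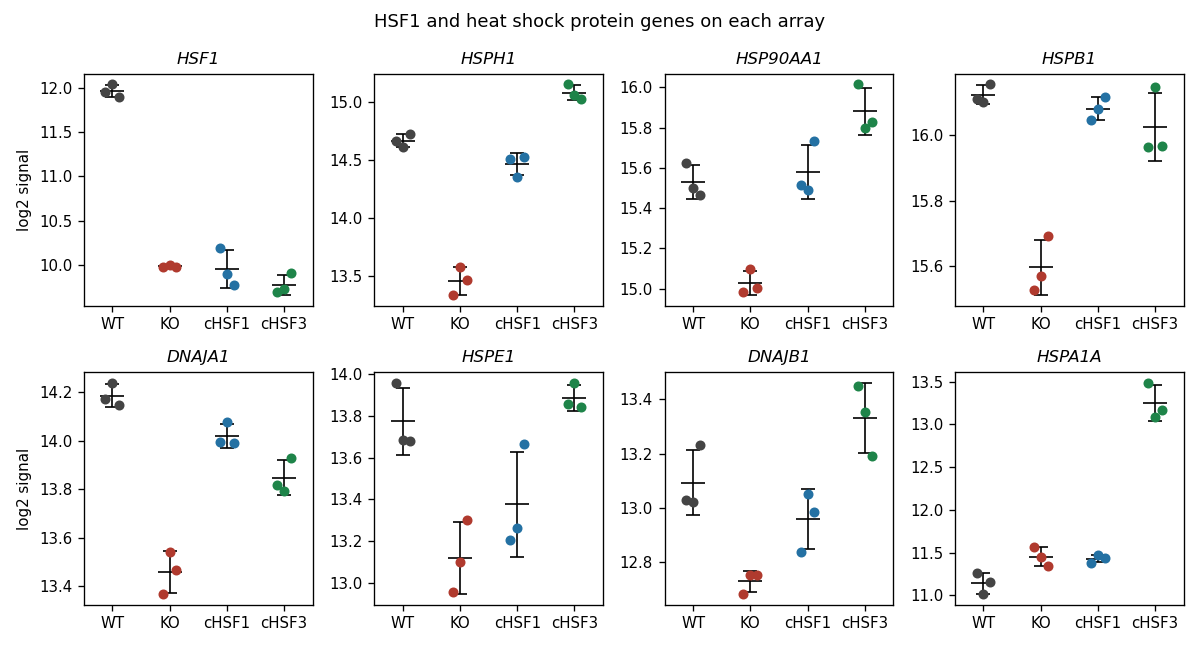
Log2 signal of HSF1 and 7 heat shock protein genes on each array (dots), with the mean (long bar) and SD (short bars) of the 3 arrays of each group. HSPH1 was 14.67 in WT, 13.46 in KO, 14.46 in cHSF1 and 15.08 in cHSF3, whereas HSPA1A was 11.14, 11.45, 11.43 and 13.25.

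Apart from HSPB6, the genes with the largest changes in KO were outside the chaperone list. Biglycan (BGN), a small proteoglycan of the extracellular matrix, was at least 20.3-fold higher in KO than in WT (12.66 against 5.13, adjusted p = 3.56e-12). "At least" marks a fold taken against the background level because the dimmer group lay under it on all 3 arrays. The BMP antagonist CHRDL1 (at least 7.75-fold), the transmembrane glycoprotein EMB (at least 5.99-fold), the adhesion protein NFASC (at least 5.11-fold) and the arginine synthesis enzyme ASS1 (at least 3.75-fold) were also higher, as were CDH11 (at least 2.88-fold), HAPLN1 (at least 2.12-fold), FNBP1L (at least 1.97-fold) and SEMA3E (at least 1.83-fold). In the other direction, the interleukin 23 receptor gene IL23R was at least 11.6-fold lower (4.92 against 12.08, adjusted p = 1.94e-09). PLPP2 (at least 8.06-fold), MAGEC2 (at least 4.72-fold), CDH6 (at least 4.20-fold), NETO1 (at least 3.46-fold), SLCO4C1 (at least 3.31-fold), CYFIP2 (at least 2.83-fold), CYSLTR1 (at least 2.18-fold) and GALNT3 (at least 1.55-fold) were lower as well.

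Extracellular matrix genes rose together in KO: 14 of 33 measured members rose, 0 fell and 19 did not pass, and 17 rose adjusted over the list alone. Besides BGN, these include the collagen chain COL6A1 (3.02-fold, 1.59 ± 0.10), fibronectin (FN1, 2.24-fold, 1.17 ± 0.08) and lumican (LUM, 2.20-fold, 1.14 ± 0.11). Contractile and TGF-beta or YAP target genes rose too, with 12 of 20 higher, 2 lower and 6 not passing (13 and 2 adjusted over the list alone). Among them, the actin-binding protein transgelin (TAGLN) was 10.2-fold higher (3.35 ± 0.16), calponin (CNN1) at least 4.52-fold, the smooth muscle actin ACTG2 at least 4.18-fold and the myosin light chain MYL9 2.19-fold (1.13 ± 0.09). Both lists passed the camera test, the matrix list with a median of 0.35 (adjusted p = 3.91e-09) and the contractile list with a median of 0.65 (adjusted p = 6.93e-08). They also passed with an estimated correlation (adjusted p = 0.00317 and 0.0188).

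Mitochondrial chaperones and proteases were lower, with 5 of 18 members lower, 1 higher and 12 not passing (6 and 1 adjusted over the list alone). Besides HSPD1 and HSPE1, the protease LONP1 fell by 0.73 ± 0.12. The list had a median of -0.10 (camera adjusted p = 0.0240), and adjusted p = 0.143 with an estimated correlation. Ribosomal protein genes were lower in KO versus WT by a small amount (median -0.10, camera adjusted p = 0.0193, adjusted p = 0.472 with an estimated correlation), with RPS21 (-0.53 ± 0.08) and RPS26 (-0.40 ± 0.10, whose call ends with the positive controls set equal) as the 2 lower members of 43, 0 higher, 41 not passing and the same counts adjusted over the list alone. When the positive controls are set equal, a scaling that moves all probe sets alike, the medians of both lists turn to 0.03 and 0.03 and the calls end (camera adjusted p = 0.0511 and 0.307). Both calls also end without WT array 1, and that of mitochondrial chaperones ends with the filter on negative controls.

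The other 19 lists tested did not pass in KO versus WT as deposited. With the positive controls set equal, ubiquitin and autophagy genes and cell cycle genes pass as higher (camera adjusted p = 0.0490 each). As deposited, the members of the 19 lists divided as follows. TRiC and prefoldin had 1 higher and 3 lower of 12 (adjusted p = 0.174), endoplasmic reticulum chaperones 6 and 2 of 25 (0.115), stress response and ATF4 targets 3 and 2 of 29 (0.759), the proteasome 1 and 1 of 29 (0.876) and ubiquitin and autophagy genes 4 and 0 of 20 (0.0975). Respiratory chain subunits had 0 higher and 5 lower of 42 (adjusted p = 0.188), cell cycle genes 3 and 1 of 43 (0.174), p53 targets 1 and 0 of 19 (0.869), inflammatory genes 3 and 2 of 27 (0.869) and interferon-stimulated genes 2 and 4 of 29 (0.250). Cholesterol genes had 0 higher and 3 lower of 25 (adjusted p = 0.174), hypoxia genes 2 and 5 of 30 (0.461), oxidative stress genes 0 and 1 of 26 (0.250), immediate early genes 4 and 3 of 26 (0.876) and HOX genes 4 and 2 of 23 (0.234). Of the marker lists of other cell types, epithelial markers had 0 higher and 2 lower of 17 (adjusted p = 0.215), endothelial markers 1 and 0 of 16 (0.250), leukocyte markers 0 and 3 of 14 (0.161), and neural, muscle and fat markers 2 and 1 of 23 (0.759). Adjusted over the list alone, these counts were the same except for endoplasmic reticulum chaperones (8 and 2), the proteasome (0 and 1), ubiquitin and autophagy genes (4 and 1), interferon-stimulated genes (3 and 5), hypoxia genes (2 and 6) and immediate early genes (7 and 5). For the inflammatory and immediate early lists the median was negative while the mean and the test were positive, and with the positive controls set equal these medians are positive. Single members with large changes include the transcription factor MYC, 3.89-fold higher (1.96 ± 0.11), the sterol reductase TM7SF2, 5.24-fold lower (-2.39 ± 0.19), and interleukin 1 beta (IL1B), 2.78-fold higher with WT above the negative controls on 2 of 3 arrays.

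In all, 2847 probe sets differed between KO and WT, 1328 higher and 1519 lower, and 1695 of them by at least 1.5-fold. Of the calls, 763 (26.8%) had both groups within the range of the negative controls. The arrays of the 2 groups did not overlap for 29.0% of the tested probe sets, against 10% by chance. The balance of directions depends on the scaling: 46.6% of the calls were higher as deposited, and 70.9% (2485 higher and 1018 lower) with the positive controls set equal.

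Chaperone genes were higher in the cells with chicken HSF1 than in KO. HSPH1 was higher in cHSF1 than in KO (14.46 against 13.46, standard error 0.10, adjusted p = 9.58e-05), as were HSP90AA1 (1.47-fold, 0.55 ± 0.10, adjusted p = 0.0112) and HSPB1 (1.40-fold, 0.48 ± 0.09, adjusted p = 0.0111). In a fit of the cHSF1 and KO arrays alone, the calls of HSP90AA1 and HSPB1 end (adjusted p up to 0.0540). The cochaperones CACYBP (0.58 ± 0.10), ST13 (0.57 ± 0.09) and DNAJA1 (0.56 ± 0.09) rose by similar amounts. HSPE1 (0.26 ± 0.14, adjusted p = 0.366), DNAJB1 (0.23 ± 0.11, 0.268), HSPD1 (0.14 ± 0.08, 0.409), BAG3 (0.12 ± 0.09, 0.553) and HSPA1A (-0.02 ± 0.12, 0.945) did not pass. Of the 33 cytosolic heat shock proteins and cochaperones, 8 rose, 0 fell and 25 did not pass (12 and 1 adjusted over the list alone). The list was higher as a whole (median 0.20, camera adjusted p = 1.33e-06, and adjusted p = 0.0158 with an estimated correlation).

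The largest changes with chicken HSF1, falls as well as rises, were of genes outside the chaperone list. The olfactory receptor gene OR51B5 was at least 6.93-fold lower (4.20 against 11.32), and its neighbours OR51B4 and HBE1, an embryonic globin gene, were at least 2.34-fold and at least 1.25-fold lower (HBE1 above the negative controls on 1 of 3 KO arrays). The cancer-testis gene PAGE1 was at least 7.64-fold lower. The collagenase gene MMP1 was at least 14.8-fold lower (8.20 against 12.41), the tight junction gene CLDN11 at least 3.41-fold lower, OLFML1 at least 1.27-fold lower and the amino acid transporter SLC38A5 52.1-fold lower (-5.70 ± 0.17, with cHSF1 above the negative controls on 2 of 3 arrays). TESPA1 and TMEM154 were lower with both groups within the range of the negative controls. In the other direction, G0S2, an inhibitor of fat breakdown, was at least 8.41-fold higher and MYD88, the adaptor of Toll-like receptors, at least 4.83-fold higher. Other genes that rose were MYO1D (at least 3.54-fold), PLEKHA7 (at least 2.66-fold), LCP1 (at least 2.53-fold), CAMK4 (at least 2.20-fold), EYA2 (at least 1.38-fold), BMP4 (at least 1.36-fold), CDKL2 (at least 1.30-fold) and GABBR2 (at least 1.30-fold).

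Targets of p53 fell with chicken HSF1. Of 19 measured, 9 fell, 1 rose and 9 did not pass (11 and 1 adjusted over the list alone). The cell cycle inhibitor CDKN1A was 1.99-fold lower (-0.99 ± 0.09, adjusted p = 8.30e-05), MDM2, the p53 ligase, 2.05-fold (-1.03 ± 0.13) and the death receptor gene TNFRSF10B 2.12-fold (-1.08 ± 0.13). The list passed the camera test (median -0.43, adjusted p = 9.52e-08) and did so with an estimated correlation (adjusted p = 0.0158). Cholesterol and SREBP target genes fell as well, with 5 of 25 lower and 0 higher (12 and 0 adjusted over the list alone), among them the synthase HMGCS1 (-1.09 ± 0.13), DHCR7 (-0.90 ± 0.12) and the desaturase SCD (-0.78 ± 0.12). Their median was -0.32 (camera adjusted p = 3.96e-08), with adjusted p = 0.210 with an estimated correlation.

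A further 7 lists passed with the preset correlation in cHSF1 versus KO, and none of these passed with the estimated one. Ribosomal proteins had 5 lower and 0 higher of 43 (11 and 0 adjusted over the list alone), including RPS14 (-0.70 ± 0.11), with camera adjusted p = 1.46e-07 and adjusted p = 0.127 with an estimated correlation. Oxidative stress genes had 3 lower and 0 higher of 26 (11 and 0 adjusted over the list alone), such as AKR1C1 (-0.79 ± 0.14), with camera adjusted p = 0.00563 and adjusted p = 0.189 with an estimated correlation. Interferon-stimulated genes had 1 lower of 29 (4 adjusted over the list alone) and 0 higher, with camera adjusted p = 0.00684 and adjusted p = 0.0937 with an estimated correlation. In this comparison and in KO versus WT, 9 of the 29 lay above the negative controls on at least 1 array of the 2 groups. Respiratory chain subunits had 1 lower of 42 and 0 higher, the same adjusted over the list alone, with camera adjusted p = 0.0150 and adjusted p = 0.444 with an estimated correlation. Stress response and ATF4 targets had 4 lower and 2 higher of 29 (9 and 3 adjusted over the list alone), with the cystine transporter SLC7A11 at -0.62 ± 0.11, camera adjusted p = 0.0347 and adjusted p = 0.358 with an estimated correlation. Cell cycle genes had 3 higher of 43 and 0 lower (5 and 0 adjusted over the list alone), with camera adjusted p = 0.0208, adjusted p = 0.189 with an estimated correlation and 0.0763 after quantile normalization. Contractile genes had 4 higher and 2 lower of 20 (7 and 2 adjusted over the list alone), with ACTG2 3.01-fold higher and the smooth muscle actin ACTA2 2.48-fold lower, camera adjusted p = 0.0208 and adjusted p = 0.189 with an estimated correlation. Without the dimmest 30% of probe sets, the calls of stress response and ATF4 targets, cell cycle genes and contractile genes end, and that of cell cycle genes ends with the filter on negative controls too. The remaining 14 lists did not pass, with adjusted p between 0.0613 and 0.843, and for TRiC and prefoldin the median was negative (positive with the positive controls set equal) while the mean and the test were positive. Of these 14, inflammatory genes pass as lower by the test with centring, with the positive controls set equal (where their median is 0.01) and with the filter on negative controls. Neural, muscle and fat markers pass as lower by the test with the positive controls set equal (median 0.00), and proteasome genes pass as lower after quantile normalization.

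In all, 966 probe sets differed between cHSF1 and KO, 509 higher and 457 lower. Of these, 613 changed by at least 1.5-fold and 245 (25.4%) had both groups within the range of the negative controls. The share of higher calls was 52.7% as deposited and 74.3% (1009 higher and 349 lower) with the positive controls set equal. The count fell to 509 without KO array 1, to 618 without KO array 2, to 637 without KO array 3, to 546 without cHSF1 array 1 and to 509 without cHSF1 array 3.

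Chaperone genes were higher in the cells with chicken HSF3 too, and HSPA1A was among them. HSPA1A was 3.47-fold higher in cHSF3 than in KO (1.79 ± 0.12, adjusted p = 3.51e-06) and HSPH1 3.07-fold (1.62 ± 0.10, adjusted p = 1.40e-06). HSP90AA1 (1.81-fold, 0.85 ± 0.10), HSPE1 (1.70-fold, 0.76 ± 0.14), DNAJB1 (1.52-fold, 0.60 ± 0.11), BAG3 (1.37-fold, 0.45 ± 0.09) and HSPB1 (1.35-fold, 0.43 ± 0.09) also rose. HSPD1 rose by 0.28 ± 0.08 (adjusted p = 0.0425), a call that ends after quantile normalization. The HSP90 cochaperone FKBP4 was 1.71-fold lower (-0.77 ± 0.08, adjusted p = 0.000183). Of the 33 cytosolic heat shock proteins and cochaperones, 15 rose, 1 fell and 17 did not pass (19 and 3 adjusted over the list alone). The list was higher (median 0.34, camera adjusted p = 1.13e-06, and adjusted p = 0.0263 with an estimated correlation), and it was the list of the 10 called that also passed with the estimated correlation.

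The OR51B and PAGE1 genes were lower with chicken HSF3 too. OR51B5 was at least 7.26-fold lower, OR51B4 at least 2.45-fold, HBE1 at least 1.31-fold and PAGE1 at least 8.01-fold. The cancer-testis gene SSX1 was 17.4-fold lower (-4.12 ± 0.09, 10.20 against 14.32), SSX8P at least 5.45-fold and SSX6P at least 5.02-fold. MAT1A, a methionine adenosyltransferase, was at least 9.63-fold lower, BCHE was 7.89-fold lower with cHSF3 above the negative controls on 1 of 3 arrays, and B3GALT1 was lower with both groups within their range. MMP1, which fell with chicken HSF1, was 9.40-fold higher with chicken HSF3 (3.23 ± 0.11, adjusted p = 1.17e-08). The growth factor gene BMP4 (at least 3.61-fold), LCP1 (at least 2.94-fold), the homeobox gene ALX1 (at least 1.52-fold, 9.15 against 2.88) and MYO1D (at least 1.37-fold) were higher, as was CD24 (6.07-fold, 2.60 ± 0.10). CDKL2, FABP4, FLRT3 and SCIN were higher with both groups within the range of the negative controls.

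**Figure D2:**
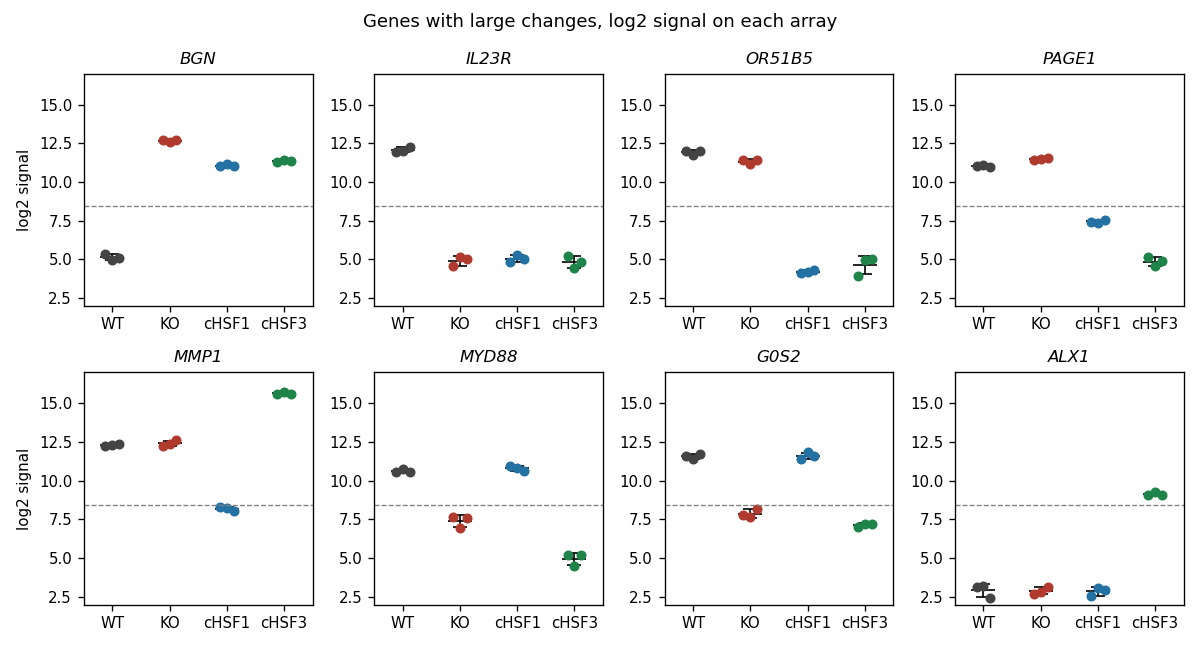
Log2 signal on each array (dots) of 8 genes with large changes, with the mean and SD of the 3 arrays of each group, where the dashed line is the mean over the arrays of the 95th percentile of the negative controls. BGN was 5.13 in WT and 12.66 in KO, OR51B5 was 11.32 in KO and 4.20 in cHSF1, and MMP1 was 8.20 in cHSF1 and 15.65 in cHSF3.

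Contractile genes rose with chicken HSF3 (8 of 20 higher and 1 lower, and 11 and 1 adjusted over the list alone), with ACTG2 3.63-fold (1.86 ± 0.16) and CNN1 3.33-fold (1.74 ± 0.19) higher. Their camera adjusted p was 0.00157, with adjusted p = 0.150 with an estimated correlation. Matrix genes had 12 higher and 2 lower of 33 (14 and 5 adjusted over the list alone). Decorin (DCN) was 3.61-fold and versican (VCAN) 2.14-fold higher, whereas BGN was 2.44-fold lower, with camera adjusted p = 0.0157 and adjusted p = 0.150 with an estimated correlation. Ubiquitin and autophagy genes had 5 higher and 0 lower of 20 (6 and 3 adjusted over the list alone), such as GABARAPL1 (0.79 ± 0.13) and the autophagy receptor OPTN (0.61 ± 0.12). Their camera adjusted p was 0.0298, with adjusted p = 0.220 with an estimated correlation and 0.0560 after quantile normalization.

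Cholesterol genes fell with chicken HSF3, with 11 of 25 lower and 0 higher (17 and 1 adjusted over the list alone), including SCD (-0.92 ± 0.12), HMGCS1 (-0.91 ± 0.13) and DHCR7 (-0.89 ± 0.12). The median was -0.42 (camera adjusted p = 4.87e-08), with adjusted p = 0.220 with an estimated correlation. Ribosomal proteins had 7 lower and 0 higher of 43, the same adjusted over the list alone, with RPS14 at -0.68 ± 0.11, camera adjusted p = 0.000753 and adjusted p = 0.220 with an estimated correlation. Respiratory chain subunits had 9 lower and 0 higher of 42 (15 and 1 adjusted over the list alone), with SDHD at -0.84 ± 0.18, camera adjusted p = 0.00862 and adjusted p = 0.365 with an estimated correlation. Oxidative stress genes had 8 lower and 0 higher of 26 (10 and 2 adjusted over the list alone), with PGD of the pentose phosphate pathway at -0.83 ± 0.13, camera adjusted p = 0.00862 and adjusted p = 0.220 with an estimated correlation. Targets of p53 had 7 lower and 0 higher of 19 (7 and 1 adjusted over the list alone), among them AEN (-0.74 ± 0.11) and GDF15 (at least 2.10-fold), with camera adjusted p = 0.00862 and adjusted p = 0.176 with an estimated correlation. Stress response and ATF4 targets had 7 lower and 3 higher of 29 (12 and 4 adjusted over the list alone), with NUPR1 4.19-fold lower (-2.07 ± 0.09) and SLC7A11 2.04-fold lower, camera adjusted p = 0.00953 and adjusted p = 0.244 with an estimated correlation.

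The other 14 lists did not pass in cHSF3 versus KO, with adjusted p between 0.0749 and 0.935. For cell cycle genes, hypoxia genes and leukocyte markers the median was negative (positive with the positive controls set equal) while the mean and the test were positive. Of these 14, proteasome genes pass as lower after quantile normalization, and inflammatory genes pass as higher without the dimmest 30% of probe sets and with the filter on negative controls. In all, 2891 probe sets differed between cHSF3 and KO, 1578 higher and 1313 lower, of which 1412 changed by at least 1.5-fold and 583 (20.2%) had both groups within the range of the negative controls. The share of higher calls was 54.6% as deposited and 71.6% (2326 higher and 924 lower) with the positive controls set equal. The count fell to 1735 without KO array 1, to 1721 without cHSF3 array 1 and to 1663 without cHSF3 array 2.

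Compared with each other, the cells with chicken HSF3 and with chicken HSF1 differed in HSPA1A, which was 3.52-fold higher with chicken HSF3 (1.82 ± 0.12, adjusted p = 5.68e-06). HSPH1 was 1.53-fold higher (0.62 ± 0.10, adjusted p = 0.00614) and FKBP4 1.97-fold lower (-0.98 ± 0.08, adjusted p = 5.37e-05). HSPE1 (0.51 ± 0.14, adjusted p = 0.127), DNAJB1 (0.37 ± 0.11, 0.133), BAG3 (0.33 ± 0.09, 0.113), HSP90AA1 (0.30 ± 0.10, 0.233), HSPD1 (0.14 ± 0.08, 0.507) and HSPB1 (-0.06 ± 0.09, 0.864) did not pass. Of the 33 cytosolic heat shock proteins and cochaperones, 2 were higher, 1 lower and 30 did not pass (8 and 4 adjusted over the list alone), and the list was not called (adjusted p = 0.0972).

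The collagenase gene MMP1 differed most between the factors, at least 139-fold higher with chicken HSF3 (15.65 against 8.20, adjusted p = 5.18e-12). SLC38A5 was 34.9-fold higher (5.12 ± 0.17, with cHSF1 above the negative controls on 2 of 3 arrays), CLDN11 at least 6.75-fold and ALX1 at least 1.54-fold. G0S2 was at least 8.91-fold lower with chicken HSF3 than with chicken HSF1, MAT1A at least 6.35-fold, MYD88 at least 5.12-fold, ZNF354C at least 1.73-fold, EYA2 at least 1.46-fold, GCSAML at least 1.13-fold and the matrix gene POSTN at least 1.01-fold. BCHE was 6.80-fold lower, with cHSF3 above the negative controls on 1 of 3 arrays. OLFML1 (8.23 against 5.10) and TMEM168 (8.29 against 5.16) were higher at levels close to the background. FABP4, SCIN and ATRNL1 were higher, and PAGE1 and RETREG1 lower, with both groups within the range of the negative controls.

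Inflammatory and NF-kB target genes were higher with chicken HSF3 than with chicken HSF1, with 4 of 27 higher and 0 lower (8 and 0 adjusted over the list alone). Besides MMP1, these were the NF-kB inhibitors TNFAIP3 (2.55-fold, 1.35 ± 0.16) and NFKBIA (1.63-fold, 0.70 ± 0.09) and IL1B (1.65-fold, 0.73 ± 0.14, with cHSF1 above the negative controls on 1 of 3 arrays and adjusted p = 0.0951 in a fit of the 2 groups alone). The list passed the camera test (median 0.22, adjusted p = 2.77e-06) and passed with an estimated correlation (adjusted p = 0.0405). Many of its members are dim: in KO versus WT and in cHSF1 versus KO, 8 of 27 lay above the negative controls on at least 1 array of the 2 groups. Matrix genes had 4 higher and 1 lower of 33 (10 and 1 adjusted over the list alone), with COL6A1 and COL6A2 at 0.76 ± 0.10 and 0.76 ± 0.14, and also passed both tests (adjusted p = 7.09e-05, and 0.0306 with an estimated correlation). Targets of p53 had 2 higher and 0 lower of 19 (7 and 0 adjusted over the list alone), CDKN1A by 0.75 ± 0.09 and MDM2 by 0.59 ± 0.13, with camera adjusted p = 0.00135 and adjusted p = 0.0690 with an estimated correlation. The MDM2 call ends after quantile normalization or centring. Immediate early genes had 2 higher and 0 lower of 26 (3 and 0 adjusted over the list alone), DUSP4 by 1.02 ± 0.12 and DUSP6 by 0.48 ± 0.10 (adjusted p = 0.0912 in a fit of the 2 groups alone), with camera adjusted p = 0.00922 and adjusted p = 0.0608 with an estimated correlation. Contractile genes had 2 higher and 0 lower of 20 (4 and 0 adjusted over the list alone), CNN1 by 1.19 ± 0.19 and ACTA2 by 1.07 ± 0.11, with camera adjusted p = 0.0195 and adjusted p = 0.238 with an estimated correlation. In the other 19 lists, none was called (adjusted p between 0.0972 and 0.904), and the median and the mean differed in sign for TRiC and prefoldin, mitochondrial chaperones, hypoxia genes, oxidative stress genes and leukocyte markers as deposited.

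In all, 400 probe sets differed between cHSF3 and cHSF1, 256 higher and 144 lower, of which 327 changed by at least 1.5-fold and 108 (27.0%) had both groups within the range of the negative controls. The count fell to 223 without cHSF1 array 1, to 227 without cHSF1 array 2, to 242 without cHSF3 array 1 and to 232 without cHSF3 array 2.

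The changes in the 2 factor groups overlapped. BMP4, LCP1, MYO1D, CDKL2 and CD24 rose in both, and OR51B5, OR51B4, PAGE1, HBE1 and SSX8P fell in both. Of the 509 probe sets higher with chicken HSF1 than in KO, 392 (77.0%) were also higher with chicken HSF3, against 37.4 for independent lists, and of the 457 lower ones 300 (65.6%) were also lower, against 28.0. Opposite calls numbered 6 and 14, against 31.2 and 33.6 for independent lists. G0S2, MYD88, GCSAML, OSBPL10 and ZNF354C are the genes with the largest changes among the 6. For G0S2, MYD88, GCSAML and ZNF354C, the fall with chicken HSF3 had both groups within the range of the negative controls. The overlap of 392 fell to 198 without KO array 1, to 221 without KO array 2, to 217 without cHSF1 array 1 and to 208 without cHSF1 array 3. Both comparisons use the KO arrays. In 20 simulations of unchanged groups sharing those arrays, the mean overlap was 0, the mean correlation of fold changes across probe sets 0.500 and the mean covariance 0.0149, whereas the observed correlation was 0.679 and the covariance 0.0836, a difference of 0.0687. No simulated group differed from another, so a low overlap was fixed in advance. The simulated overlap therefore does not measure chance for groups that do differ. The excess over either reference is not called a shared effect, and since 3 arrays cannot be split into parts of 2 or more, part of it may come from the shared arrays. Handling common to both factor groups and absent from KO cannot be told apart from the factors either.

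Some genes lowered in KO rose with a chicken factor. The protease gene CTSK, 7.42-fold lower in KO than in WT (-2.89 ± 0.12), was 3.83-fold higher with chicken HSF1 and 4.08-fold higher with chicken HSF3 than in KO. NPTX1, a neuronal pentraxin gene, was 4.87-fold lower in KO and rose 5.64-fold and 4.23-fold. G0S2 (at least 8.20-fold lower in KO) and MYD88 (at least 4.22-fold lower in KO) rose with chicken HSF1 to levels that did not differ from WT (adjusted p = 0.906 and 0.575). With chicken HSF1, 104 probe sets lower in KO rose, against 36.0 for independent lists, and 69 of them were not called against WT. With chicken HSF3 the count was 189, against 112, and 119 were not called against WT. A missing call does not show a return to the level of WT. These overlaps fell to 68 and 118 without KO array 1. In the opposite pattern, higher in KO and lower with the factor, the counts were 98 against 28.3 with chicken HSF1 and 113 against 81.3 with chicken HSF3. CHRDL1 is an example, 6.12-fold lower with chicken HSF1 and 6.92-fold lower with chicken HSF3 than in KO, each with the factor group above the negative controls on 2 of 3 arrays.

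Other genes moved further from WT. CLDN11, 5.23-fold lower in KO than in WT, fell again with chicken HSF1, and the receptor gene KIT and the calcineurin regulator RCAN2 were higher in KO and rose again with either factor (KIT by 1.65 ± 0.11 and 1.88 ± 0.11, RCAN2 by 1.41 ± 0.13 and 1.81 ± 0.13). With chicken HSF1, 108 probe sets lower in KO fell again and 111 higher ones rose again, against 32.4 and 31.5 for independent lists. With chicken HSF3 the counts were 218 and 289, against 93.0 and 97.7. All of these overlaps share the KO arrays, and the same simulations gave a mean of 0 for each, a low value fixed in advance here too. The correlation between the KO versus WT change and the change with the factor was -0.049 for chicken HSF1 and -0.00266 for chicken HSF3, against -0.500 and -0.499 in the simulations. The covariances were -0.00749 and -0.000482, against -0.0149 and -0.0148, differences of 0.00739 and 0.0144. The simulated correlations are negative, so sharing the KO arrays works against calls in the same direction. This argues against the shared arrays as the source of the excess of 108, 111, 218 and 289 over independent lists. The excess is still not called a shared effect.

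Many probe sets called in KO versus WT were also called in the cells with a chicken factor versus WT. Of the 2847 probe sets called in KO versus WT, 2292 (80.5%) were called in the same direction in cHSF1 versus WT, 28 in the opposite direction and 527 not at all. For cHSF3 these were 2295 (80.6%), 40 and 512. Independent lists would share 336 and 421 in the same direction. These comparisons use the same WT arrays. In 20 simulations that share them, with the factor groups set at the level of WT and KO at its own, at most 1 probe set called in KO was also called in the same direction in either factor group. These simulations called a mean of 0.05 probe sets against WT in each factor group, so a low overlap was fixed in advance. Their mean number of KO calls was 4457, against 2847 observed. The excess over these references is not called a shared effect. IL23R stayed at least 11.7-fold lower with chicken HSF1 and at least 12.3-fold lower with chicken HSF3, and SLCO4C1 stayed lower in both, at least 3.34-fold with chicken HSF1. BGN stayed at least 6.70-fold and at least 8.33-fold higher, NFASC at least 5.06-fold and at least 4.69-fold higher. OR51B5 (11.91 in WT, 4.20 in cHSF1 and 4.64 in cHSF3) added to these, as did TMEM154 (at least 5.79-fold and at least 6.07-fold lower), CLDN11 in cHSF1 (at least 17.8-fold lower), and OR51B4 (at least 8.63-fold lower) and NETO1 (at least 3.66-fold lower) in cHSF3. EDIL3 (at least 8.46-fold), HSPB6 (28.2-fold, with WT above the negative controls on 2 of 3 arrays) and SEMA3E (at least 1.18-fold) were higher in cHSF1 than in WT, and RCAN2 (at least 6.34-fold), CDH11 (at least 5.34-fold) and ALX1 (at least 1.78-fold) in cHSF3.

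Several heat shock genes were not called against WT with chicken HSF1, namely HSPH1 (-0.20 ± 0.10, adjusted p = 0.171), HSP90AA1 (0.05 ± 0.10, 0.804), HSPB1 (-0.04 ± 0.09, 0.813), DNAJB1 (-0.13 ± 0.11, 0.423), HSPE1 (-0.40 ± 0.14, 0.0633), HSPA1A (0.29 ± 0.12, 0.110) and BAG3 (0.10 ± 0.09, 0.491), while HSPD1 stayed lower (-0.45 ± 0.08, 0.00167). A missing call does not show the level of WT, and HSPE1 and DNAJB1 were not called against KO either. With chicken HSF3, HSPA1A was 4.30-fold above WT (2.10 ± 0.12, adjusted p = 1.61e-07), and BAG3 (0.44 ± 0.09), HSPH1 (0.42 ± 0.10) and HSP90AA1 (0.35 ± 0.10) were higher too. The HSP90AA1 call ends in a fit of the 2 groups alone (adjusted p = 0.0614). HSPD1 (-0.31 ± 0.08) was lower, a call that ends with the positive controls set equal (adjusted p = 0.313), and HSPE1 (0.11 ± 0.14, adjusted p = 0.616), DNAJB1 (0.24 ± 0.11, 0.116) and HSPB1 (-0.10 ± 0.09, 0.482) did not pass. Of the 33 cytosolic chaperones and cochaperones, 4 were higher and 3 lower than in WT with chicken HSF1 (the same adjusted over the list alone) and 10 higher and 8 lower with chicken HSF3 (11 and 9 adjusted over the list alone). The list was called in neither comparison (adjusted p = 0.893 and 0.250). For cHSF1 its median was -0.05, which turns to 0.16 with the positive controls set equal, while the mean was 0.12.

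Matrix and contractile genes were higher than in WT in both factor groups, and these were the lists that also passed with an estimated correlation. Matrix genes had 15 higher and 0 lower of 33 in cHSF1 and 19 and 2 in cHSF3 (17 and 1, and 21 and 2, adjusted over the list alone), with adjusted p = 0.00896 and 0.00523 with an estimated correlation. DCN was 3.44-fold and 4.59-fold higher, FN1 2.27-fold and 2.88-fold. Contractile genes had 12 higher and 4 lower of 20 in cHSF1 and 15 and 2 in cHSF3 (13 and 4, and 15 and 2, adjusted over the list alone), with adjusted p = 0.0434 and 0.0220 with an estimated correlation. TAGLN was 13.7-fold and 19.3-fold higher and MYL9 2.41-fold and 2.72-fold. Cholesterol genes had 15 lower and 1 higher of 25 in cHSF1 and 18 and 1 in cHSF3 (16 and 1, and 18 and 1, adjusted over the list alone), with HMGCS1 3.05-fold and 2.69-fold lower. They passed with the preset correlation (camera adjusted p = 2.89e-06 and 4.76e-07) and not with the estimated one (adjusted p = 0.315 and 0.256 with an estimated correlation).

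Of the 24 lists, 11 were called in cHSF1 versus WT and 9 in cHSF3 versus WT, and the following passed with the preset correlation alone. Ribosomal proteins had 18 lower and 0 higher of 43 in cHSF1 (camera adjusted p = 1.64e-07, adjusted p = 0.0743 with an estimated correlation) and 17 and 1 in cHSF3 (9.12e-06, adjusted p = 0.198 with an estimated correlation), with RPS14 lower by 0.92 ± 0.11 and 0.90 ± 0.11. Their medians were -0.21 and -0.23, and with the positive controls set equal they lie at -0.01 and -0.03, with 8 lower and 1 higher in cHSF1 and 7 lower and 4 higher in cHSF3, while the list stays called. Mitochondrial chaperones and proteases had 8 lower and 1 higher of 18 in cHSF1 (camera adjusted p = 0.00937, adjusted p = 0.0743 with an estimated correlation) and 9 and 1 in cHSF3 (0.0193, adjusted p = 0.198 with an estimated correlation), with TRAP1, the mitochondrial HSP90, lower by 0.62 ± 0.11 and 0.80 ± 0.11. Ubiquitin and autophagy genes had 7 higher and 2 lower of 20 in cHSF1 (camera adjusted p = 0.0275, 0.0506 after quantile normalization, adjusted p = 0.244 with an estimated correlation) and 9 and 2 in cHSF3 (0.00949, adjusted p = 0.198 with an estimated correlation). Respiratory chain subunits had 9 lower and 1 higher of 42 in cHSF1 (camera adjusted p = 0.00891, adjusted p = 0.421 with an estimated correlation) and 14 and 2 in cHSF3 (0.00561, adjusted p = 0.317 with an estimated correlation), with UQCRH lower by 0.95 ± 0.09 and 0.96 ± 0.09. With the positive controls set equal, the median of this list turns from -0.18 to 0.02 in cHSF1 and the call ends (adjusted p = 0.0558), and in cHSF3 the median goes from -0.21 to -0.01, with 8 lower and 9 higher. Oxidative stress genes had 10 lower and 1 higher of 26 in cHSF1 (camera adjusted p = 0.0119, adjusted p = 0.255 with an estimated correlation) and 12 and 1 in cHSF3 (0.0153, adjusted p = 0.256 with an estimated correlation), and with the positive controls set equal their medians turn from -0.07 to 0.13 and from -0.18 to 0.02, with the call in cHSF1 ending (adjusted p = 0.0713).

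In cHSF1 alone, p53 targets had 11 lower and 1 higher of 19 (camera adjusted p = 0.000495, adjusted p = 0.0743 with an estimated correlation), with TNFRSF10B 2.64-fold and CDKN1A 1.87-fold lower. Interferon-stimulated genes had 10 lower and 2 higher of 29 (camera adjusted p = 0.0101, adjusted p = 0.0743 with an estimated correlation), with IFITM3, an antiviral membrane protein, 1.53-fold lower. Cell cycle genes had 13 higher and 2 lower of 43 (camera adjusted p = 0.00937, adjusted p = 0.148 with an estimated correlation), with the kinetochore gene CENPE higher by 0.76 ± 0.10. In cHSF3 alone, stress response and ATF4 targets had 12 lower and 3 higher of 29 (camera adjusted p = 0.0153, adjusted p = 0.256 with an estimated correlation), with NUPR1 2.96-fold and SLC7A11 2.11-fold lower. With the positive controls set equal, the median of interferon-stimulated genes in cHSF1 goes from -0.24 to -0.04 (7 lower and 3 higher) and that of stress response and ATF4 targets in cHSF3 from -0.29 to -0.10 (8 lower and 6 higher), and both stay called. Adjusted over the list alone, the lower and higher members in cHSF1 were 21 and 0 for ribosomal proteins, 9 and 1 for mitochondrial chaperones, 10 and 1 for respiratory chain subunits and 2 and 15 for cell cycle genes, and in cHSF3 20 and 1, 9 and 2, and 15 and 2 for the same lists up to respiratory chain subunits. Ubiquitin and autophagy genes then had 10 higher and 2 lower in both groups, and the oxidative stress, p53, interferon and ATF4 lists kept their counts. A list called against WT in 1 factor group and not in the other is not thereby shown to differ between them. The lists not called had adjusted p between 0.0967 and 0.893 in cHSF1 versus WT and between 0.0985 and 0.959 in cHSF3 versus WT. The median and the mean differed in sign for epithelial markers and for neural, muscle and fat markers in cHSF1, and for the latter in cHSF3. With the positive controls set equal, cell cycle genes pass as higher in cHSF3 versus WT (camera adjusted p = 0.0339), and interferon-stimulated genes pass as lower by the test (0.0454) with a median of 0.10.

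In all, 5060 probe sets differed between cHSF1 and WT, 2507 higher and 2553 lower, and 6351 between cHSF3 and WT, 3209 higher and 3142 lower. Both groups lay within the range of the negative controls for 1176 (23.2%) and 1513 (23.8%) of these. The share of higher calls was 49.5% and 50.5% as deposited, and 78.3% (5239 higher and 1454 lower) and 75.8% (5831 higher and 1866 lower) with the positive controls set equal. The groups did not overlap for 38.1% and 42.1% of the tested probe sets, against 10% by chance.

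Some calls given above end when 1 array is left out. Of the lists, cell cycle genes in cHSF1 versus KO are not called without KO array 2 or cHSF1 array 3, stress response and ATF4 targets and contractile genes without KO array 3 or cHSF1 array 3, and respiratory chain subunits without KO array 3 or cHSF1 array 1. In cHSF3 versus KO, ubiquitin and autophagy genes are not called without KO array 2 or cHSF3 array 3, matrix genes without KO array 2 and respiratory chain subunits without KO array 3. Contractile genes in cHSF3 versus cHSF1 are not called without cHSF1 array 1, cHSF1 array 2 or cHSF3 array 1. Lists not called as deposited that pass with 1 array left out are ubiquitin and autophagy genes (without WT array 2 or KO array 2), epithelial markers (KO array 2) and cholesterol genes (KO array 3) in KO versus WT, inflammatory genes (KO array 2 or cHSF1 array 2) and neural, muscle and fat markers (cHSF1 array 1) in cHSF1 versus KO, and cholesterol genes (cHSF1 array 3) in cHSF3 versus cHSF1. Lists compared with WT in the factor groups were not tested with arrays left out. Of the heat shock genes, DNAJB1 in KO versus WT and HSPD1 in cHSF3 versus KO lose their call whichever array of the 2 groups is left out. In cHSF1 versus KO, HSP90AA1 loses it without KO array 1 or cHSF1 array 3 and HSPB1 without KO array 1, and in cHSF3 versus WT HSP90AA1 loses it without WT array 2, WT array 3 or cHSF3 array 1. Among the other genes named, RPS26 in KO versus WT, OSBPL10 in cHSF1 versus KO, G0S2 in cHSF3 versus KO, and IL1B, MDM2, DUSP6 and COL6A2 in cHSF3 versus cHSF1 lose their call without at least 1 of the arrays.

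**Figure D3:**
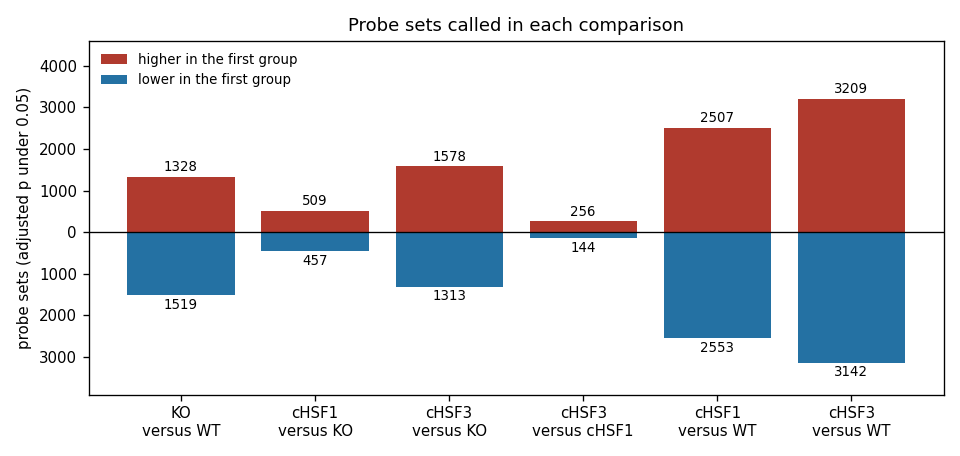
Number of probe sets called in each comparison of 2 groups (adjusted p under 0.05), with those higher in the group named before "versus" drawn upwards and those lower drawn downwards from 0. KO versus WT had 1328 higher and 1519 lower, and cHSF3 versus cHSF1 had 256 higher and 144 lower.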

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

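The scaling on positive controls and the filter on negative controls were chosen after seeing the data. Of 591 calls for named genes, 514 passed in the same direction under every alternative in which the gene was tested, left-out arrays included. Dim genes that a filter removed were not tested under it, and the minimum change of 1.5-fold was not applied to single genes or lists. Of 30 list calls, 7 passed in the same direction under every alternative run for lists, or 20 without the estimated correlation. No gene or list call turned to a call in the opposite direction. The medians of called lists that change sign with the positive controls set equal are named in the results. The precision is limited by 3 arrays per group and, for dim genes, by signal over background, since 41.0% to 45.9% of the tested probe sets lie above the 95th percentile of the negative controls. Quantile normalization, centring, array weights and 1 probe set per gene kept every count of called probe sets within 1.5 times its value. The first 3 did so too for the counts of lists, which were run for KO versus WT, cHSF1 versus KO, cHSF3 versus KO and cHSF3 versus cHSF1.

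Fitting the arrays of the compared groups alone gave 1830 probe sets in KO versus WT, 533 in cHSF1 versus KO and 233 in cHSF3 versus cHSF1. Fewer arrays then set the spread. A minimum change of 1.5-fold, which by construction leaves fewer, gave 1695 in KO versus WT, 613 in cHSF1 versus KO, 1412 in cHSF3 versus KO, 2859 in cHSF1 versus WT and 3747 in cHSF3 versus WT, and 62, 98 and 207 for the overlaps of lower in KO with higher in cHSF1, lower in KO with higher in cHSF3, and higher in both factors. Leaving out the dimmest 30% of probe sets gave 1488 in cHSF1 versus KO and 616 higher in both factors. The variance trend with a robust prior gave 2000 in cHSF1 versus KO, 737 in cHSF3 versus cHSF1 and 823 higher in both. Setting the positive controls equal gave 769 higher in both. The filter on negative controls gave 1834 in cHSF1 versus KO, 632 in cHSF3 versus cHSF1, 160 lower in KO and higher in cHSF1, and 812 higher in both. For these rises the cause was not tested. With an estimated correlation, 2, 2, 1 and 2 lists were called in KO versus WT, cHSF1 versus KO, cHSF3 versus KO and cHSF3 versus cHSF1, against 5, 10, 10 and 5.

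With each array left out in turn, which leaves fewer arrays in a group, the counts ranged from 2122 to 2326 in KO versus WT, from 509 to 724 in cHSF1 versus KO, from 1663 to 2347 in cHSF3 versus KO, from 223 to 282 in cHSF3 versus cHSF1, from 3952 to 4467 in cHSF1 versus WT and from 5217 to 5682 in cHSF3 versus WT. Overlaps ranged from 68 to 95 for lower in KO and higher in cHSF1, from 118 to 175 for lower in KO and higher in cHSF3, and from 198 to 423 for higher in both. The number of lists called ranged from 3 (without WT array 1) to 7 in KO versus WT, from 7 to 11 in cHSF1 versus KO, from 8 to 10 in cHSF3 versus KO and from 4 to 6 in cHSF3 versus cHSF1.

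The arrays share replicate numbers that the labels do not say pair them. The deviations of same-numbered arrays from their group means correlated between -0.171 and 0.0902 over 18 pairs, 0 of them over 0.1. With the replicate number as a block, 2478 probe sets were called in KO versus WT, 697 in cHSF1 versus KO, 2418 in cHSF3 versus KO and 288 in cHSF3 versus cHSF1.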

Other observations

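The tests of neighbouring genes were chosen after the OR51B, HBE1 and SSX examples had been seen, and the tests of the movement back towards WT and of chaperone genes were chosen only after the result was seen.

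Some further genes of the marker, autophagy and oxidative stress lists differed from WT, the leukocyte gene HLA-DRA and the neuronal gene MAP2 in KO, cHSF1 and cHSF3. HLA-DRA, which encodes a class II antigen, was 8.93 ± 0.25 in WT and lower by at least 1.31-fold in KO, at least 1.33-fold in cHSF1 and at least 1.39-fold in cHSF3. The neuronal microtubule gene MAP2 was higher than in WT by 1.46 ± 0.13 in KO, 1.01 ± 0.13 in cHSF1 and 1.15 ± 0.13 in cHSF3. The muscle gene TNNT1 was 4.20-fold lower in cHSF1 and 2.58-fold lower in cHSF3 than in WT. The autophagy genes GABARAPL1 (1.85-fold and 3.09-fold) and OPTN (1.98-fold and 2.23-fold) were higher than in WT with chicken HSF1 and with chicken HSF3. The redox gene AKR1C1 was 3.06-fold and 3.49-fold lower.

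Genes called in the same direction were chromosomal neighbours more often than in shuffles of the calls, which were not matched on signal. Over 17658 ordered genes, 290 adjacent pairs were called in the same direction in KO versus WT, 58 in cHSF1 versus KO and 279 in cHSF3 versus KO, above the level that at most 2.5% of 10000 shuffles exceeded (204, 31 and 205, permutation p = 0.0001 each, the smallest they can give). Runs of at least 3 adjacent genes with changes of at least 2-fold were HBE1, OR51B4, OR51B2 and OR51B5 on chromosome 11 and SSX5, SSX1 and SSX9P on X, lower with both factors, SSX8P, SSX7 and SSX2B on X, lower with chicken HSF3, and ADGRF5, ADGRF1 and TNFRSF21 on 6, several CGB genes on 19 (lower), ZNF genes on 19 and PCBP3, COL6A1 and COL6A2 on 21 (higher) in KO. A gene family was taken as symbols that share their letters before the first digit. Signal shared between members of such a family does not account for all of the excess, since without pairs of the same family the counts were 229, 39 and 235 against levels of 183, 28 and 184. A change in dosage of whole chromosomes does not either, since shuffles within chromosomes gave levels of 208, 33 and 208 for 290, 58 and 279. Changes of smaller regions, in copy number or in chromatin, may underlie such runs and were not tested.

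Of 2847 probe sets called in KO versus WT, 2292 and 2295 were called in the same direction against WT with chicken HSF1 and chicken HSF3. Over the probe sets called in KO versus WT, the median shift from WT was 0.650 in KO. It was 0.706 with chicken HSF1 and 0.755 with chicken HSF3. With each of 12 arrays left out, it was at least as large in the factor groups as in KO. This argues against a movement back towards WT of these probe sets as a whole. The median also covers probe sets called as moving back or further away. Movement under the threshold in a part of them is therefore not excluded. The WT arrays are shared and probe sets were chosen by their calls in KO, so part of each shift may come from this, and simulations with the factor groups at the level of WT gave mean shifts of 0.0468 and 0.0460. A difference between the wild-type cells and the knockout-derived line that does not depend on HSF1 cannot be told apart from loss of HSF1 for the 2292 and 2295 probe sets still called, since the labels name no separate knockout lines. Loss of functions that human HSF1 has and the chicken factors lack remains open as well and was not tested.

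Of the chaperone genes lowered in KO, a larger share rose with the factors than of other lowered genes. Of 15 such genes, 8 rose with chicken HSF1 (53.3%) against 89 of 1316 other lowered genes (6.76%, two-sided Fisher's exact p = 2.53e-06), and 10 rose with chicken HSF3 (66.7%) against 163 (12.4%, p = 1.81e-06 by the same exact test). The list was singled out after these values were seen and the tests treat its genes as independent, so the p-values do not exclude equal return of all lowered genes. Those that rose with both were CACYBP, DNAJA1, HSP90AA1, HSPB1, HSPH1 and ST13. In 10000 sets of other lowered genes matched on signal, the highest number that rose was 4 with chicken HSF1 and 7 with chicken HSF3 (permutation p = 0.0001 each, the smallest they can give). Other lowered genes of similar signal thus rose less often. The matched sets held a mean of 0.52 genes that rose with chicken HSF1 and 1.66 with chicken HSF3. This argues against high signal as the account for the rise of these chaperone genes. The limits of the exact tests hold for the permutation p-values too. Whether the genes are direct targets of the factors stays open, as the series holds no binding data.

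Other splits of the arrays were counted for each model. For any difference among the 4 groups, 1 of 100 splits of the 12 arrays, the real one, gave as many as 6189 probe sets, and the highest other gave 2580, so chance assignment of arrays is excluded for this count. The overlaps of 104, 189 and 392 were each reached by 1 of 100 splits, the real one, with 0, 0 and 1 as the highest other. Of the 99 other splits, 98, 96 and 94 called no probe set in KO versus WT, cHSF1 versus KO and cHSF3 versus KO. Overlaps in splits without calls are 0 whether or not the changes are related, so chance is not called excluded for the overlaps of 104, 189 and 392. The highest counts among the 99 were 162, 42 and 4388, the last above the real 2891 in cHSF3 versus KO. For comparisons of 3 against 3 arrays, the 10 splits are too few for a share under 0.05. There the real split gave 2847, 966, 2891, 400, 5060 and 6351 probe sets in KO versus WT, cHSF1 versus KO, cHSF3 versus KO, cHSF3 versus cHSF1, cHSF1 versus WT and cHSF3 versus WT, and the highest other 0, 0, 0, 0, 1 and 0. In the same order, the real split gave 5, 10, 10 and 5 gene lists in the 4 comparisons tested, and the highest other 4, 5, 3 and 3.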
